A study of Mus musculus with 3 samples.

How the data were processed

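Reduced representation bisulfite sequencing of mouse whole heart was analysed for 3 libraries, mG4H-ON, mG4H-OFF and Con-OFF, each a pool of 10 animals per the submitters' series design text, with 1 library per group. A Con-ON group is named in the labels and was not analysed here. Libraries were made with the Zymo Methyl-MidiSeq kit per the labels' protocols. Reads were checked with FastQC 0.11.9, trimmed with Trim Galore, aligned and called with Bismark and compared with methylKit 1.16.1 on build mm39, per the submitters' processing notes, which give no version for Trim Galore and Bismark.

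The deposited data were 12 tables, 4 for each of 3 comparisons, limited by the authors to p under 0.05 or q under 0.1, each without and with a difference of more than 5 percentage points. Each table gives read counts as the coverage of a cytosine in each of 2 libraries, per the file headers; the lowest coverage was 10 reads. Methylation is deposited as a percent of the reads covering the cytosine, per the file headers, and every percent times its coverage was a whole number of reads within the rounding of the deposited decimals. The deposited difference is in percentage points between the 2 libraries, per the file headers. The p-value and q-value of each site are the authors', per the file headers. The ratio of q to p gave 2391223 sites tested in each comparison, as in a Benjamini-Hochberg adjustment. The implied ranks put 1180 (mG4H-OFF against Con-OFF), 909 (mG4H-ON against Con-OFF) and 42 (mG4H-OFF against mG4H-ON) sites at q under 0.1. Of these, 97, 41 and 23 in that order were not in the tables used here. Which percent column belongs to which library was taken from the table names and column order.

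A site carries a line for each annotation in these tables, and lines were merged to 1 site per chromosome, position and strand before counting. Gene symbols, gene parts and CpG island classes (11 classes) are those in the deposited tables. The gene coordinates at hand were on another genome build and were not used, and no genome sequence was used, so sequence context was not examined. Sites at p under 0.05 numbered 51594, 48122 and 41094 in the 3 comparisons in the order above, which is 2.16%, 2.01% and 1.72% of the sites tested, where 119561 would be listed if p were uniform. It was not uniform in the simulated data described below, where 3.13%, 3.09% and 3.27% of unchanged sites had p under 0.05.

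A site was called at the authors' q under 0.1 with a difference of more than 5 percentage points. The deposited p-value was checked with Fisher's exact test on the counts rebuilt from percent and coverage, and it was equal within 0.1% at all 3000 sites checked in each comparison. Levels and shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Annotation classes were compared between called sites and sites listed at p under 0.05 that missed the q threshold with Fisher's exact test over sites, adjusted by Benjamini-Hochberg over the 11 classes. Called sites within 500 bp were merged to regions. Median coverage at called sites was 93 reads in mG4H-OFF and 61 in Con-OFF, 76 in mG4H-ON and 59.5 in Con-OFF, and 432 in mG4H-OFF and 368.5 in mG4H-ON.

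The overlap of the comparisons with Con-OFF was counted per direction beside the product of the list lengths over the sites tested. It was also set beside 98 simulated sets of 24597 sites in which 3 libraries with the real coverages had the same methylation. These were the sites listed in at least 2 comparisons, since all 3 coverages were known only there. The usual range of the coverage ratio of 2 libraries was the 10th to 90th percentile of sites that missed the q threshold.

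For 24 gene lists with 586 genes, called members and the median difference over sites listed at p under 0.05 with more than 5 points were computed. The median was ranked among 10000 random lists matched on the numbers of listed sites. The lists, the comparisons, the thresholds and the alternatives planned were fixed before the data were examined. Named genes followed a rule fixed at the same time, with exceptions stated here. The rule took up to 10 genes per direction by net number of called sites, up to 5 single sites per direction by size of difference, and every list gene with a called site, up to 5 per list by q. It also took Slc2a4 and Myh6 whatever their values, and up to 10 genes per direction by number of shared sites. List members beyond 5 in a list, the members of lists named in the comparison of mG4H-OFF with mG4H-ON, the ribosomal RNA sites and the genes in the part on other observations were chosen after their values were seen. Not every gene the rule named is reported here.

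Alternatives were other q, p and difference thresholds, at least 20 reads in both libraries, regions in place of sites, removal of chromosomes X and Y, removal of complete differences at 0 or 100%, Fisher's exact test adjusted over the listed sites, counting of every annotation line and, for the lists, promoter sites or called sites only. Added after the data were examined were removal of Rn45s and Rn18s, removal of sites at 10% or less or 90% or more in Con-OFF, and restriction to the usual coverage ratio. The calling rule was tested on simulated data of 20000 sites per comparison with the real coverages. The adjustment there ran over these 20000 sites and not over the 2391223 tested. Its threshold was thus laxer than that of the deposited q, and the recovered shares are too high for the deposited calls. Planted differences of 10, 25 and 50 points were recovered at 8%, 36% and 74% of sites for mG4H-OFF against Con-OFF and at 4%, 24% and 77% for mG4H-ON against Con-OFF, and 4 and 9 of 19800 unchanged sites were called. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.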

Results

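DNA methylation was measured in whole hearts of mice by reduced representation bisulfite sequencing, which reads cytosine methylation mainly in the CpG-rich part of the genome. The mG4H mouse carries a transgene that raises the glucose transporter GLUT4 in cardiomyocytes when doxycycline (DOX) is given, so that glucose delivery to these cells can be switched on and off. Hearts of 10 animals were pooled into 1 library per group. The mG4H-ON library came from transgenic mice after 2 weeks of DOX. The mG4H-OFF library came from transgenic mice given DOX for 2 weeks and then kept without it for another 2 weeks, and the Con-OFF library from control mice on that same schedule. No group had a replicate library, so no difference between groups could be set against animal-to-animal variation, and each test per site compared 2 libraries, not 2 conditions. Intervals on methylation levels are exact Clopper-Pearson 95% intervals and cover counting error only.

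The number of CpG sites tested was 2391223 in each of the 3 comparisons, as implied by the ratio of q to p in the authors' deposited table. Every listed site had at least 10 reads in both libraries. At the sites listed at p under 0.05, median coverage was 39 reads in mG4H-OFF and 47 in Con-OFF in the comparison of these libraries, and 31 reads in mG4H-ON against 47 in Con-OFF. A site was called when q was under 0.1 and the methylation levels differed by more than 5 percentage points. Positions are on mouse genome build mm39, and gene and CpG island annotations are those given with the sites.

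The comparison of mG4H-OFF with Con-OFF addressed whether methylation differed in hearts that had received extra glucose and had then returned to basal uptake for 2 weeks. Methylation differed at 1026 CpG sites annotated to 879 genes, and it was lower in mG4H-OFF at 669 of them and higher at 357. The sites with lower methylation included CpGs at genes of mitochondrial oxidation (Uqcrc2, Idh3a, Mdh2), at Prkag2, which encodes a regulatory subunit of the AMP-activated protein kinase, at the endothelin receptor gene Ednra, and at Jarid2, which encodes an accessory subunit of the Polycomb repressive complex. Methylation was higher at a CpG in Itpr1, the gene of a calcium release channel of the endoplasmic reticulum, and at a CpG in Tet2, which encodes an enzyme that oxidises methylated cytosine. Except at Tet2 and part of the Jarid2 sites, coverage in mG4H-OFF relative to Con-OFF was unusually high at these named sites, as given below. The median size of the difference was 43.7 percentage points, and the share of higher sites was 34.8% (95% interval 31.9 to 37.8%).

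The differences started mostly from the extremes of methylation in the control library. Con-OFF was methylated at 90% or more at 494 of the 1026 sites, where the median level was 98.0% in Con-OFF and 46.6% in mG4H-OFF. It was methylated at 10% or less at 261 sites, with medians of 1.03% and 43.8%. At the remaining 271 sites the medians were 55.1% in Con-OFF and 37.9% in mG4H-OFF.

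**Figure D1:**
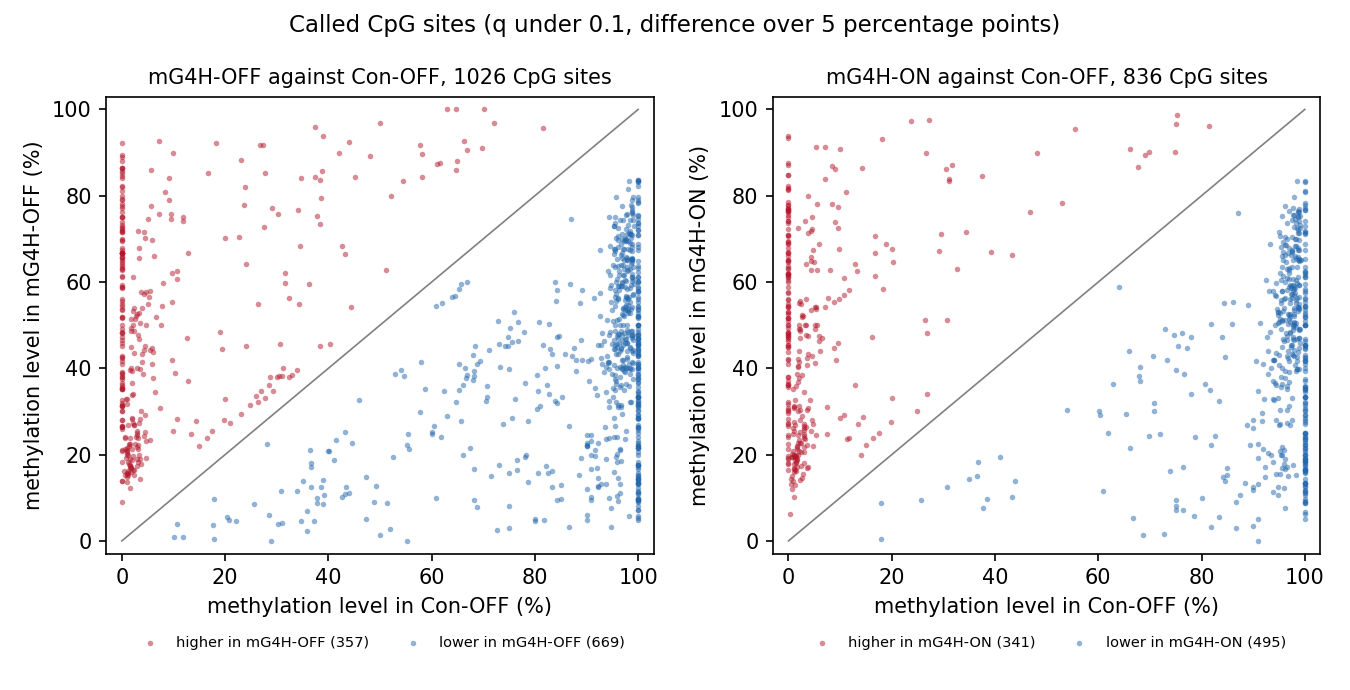
Methylation level in Con-OFF (x axis, %) against the level in mG4H-OFF (left, 1026 sites) or mG4H-ON (right, 836 sites) at the called CpG sites, each point being 1 site in 1 pair of pooled libraries. Red points were higher and blue points lower in the mG4H library, and most points lie at 10% or less or at 90% or more on the x axis and at intermediate levels on the y axis.

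Called sites lay near gene starts and in CpG islands more often than listed sites that missed the q threshold. CpG islands held 42.0% of the called sites and 9.77% of the sites that passed p under 0.05 alone (Fisher's exact test over sites of these 2 libraries, Benjamini-Hochberg adjusted p = 7.52e-155), and promoters held 24.7% and 5.26% (adjusted p = 6.03e-91). Intergenic sites made up 20.3% of the called sites and 37.7% of the others (Fisher's exact test, adjusted p = 3.16e-32). The share in introns was 40.6% and 39.6% (Fisher's exact test, adjusted p = 0.519). The sets were not matched on depth. Median coverage in mG4H-OFF and Con-OFF was 93 and 61 reads at called sites, and 36 and 45 at all sites listed with more than 5 points. How far the shares follow from depth was not tested.

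Of the 24 gene lists fixed beforehand, 15 had at least 1 called site in this comparison, with 37 genes between them. The number of called members was within the central 95% of random gene lists, matched on their numbers of listed sites, for every list. Random lists held on average 1.25 called members for oxidative phosphorylation, 4.03 for calcium handling, 2.29 for hypertrophy and stress, 2.34 for insulin signalling and 3.12 for histone modifying enzymes. In the list of oxidative phosphorylation and mitochondrial biogenesis, 3 of 46 genes had a called site and all 3 sites were lower in mG4H-OFF. The promoter CpG of Uqcrc2, a core subunit of respiratory complex III, at position 120234316 of chromosome 7 was methylated at 12.4% in mG4H-OFF (89 reads, 6.33 to 21.0%) and at 100% in Con-OFF (19 reads, 82.4 to 100%). The promoter CpG of Idh3a, a subunit of mitochondrial isocitrate dehydrogenase, at position 54493650 of chromosome 9 stood at 15.3% (72 reads) against 100% (14 reads). The promoter and exon CpG of Mdh2, mitochondrial malate dehydrogenase, at position 135807121 of chromosome 5 stood at 29.2% (120 reads) against 100% (12 reads).

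Genes of insulin and growth signalling went both ways, with called sites in 4 of 31 list members. The promoter island CpG of Prkag2 at position 25305009 of chromosome 5 was methylated at 3.26% in mG4H-OFF (92 reads, 0.678 to 9.23%) and at 94.7% in Con-OFF (19 reads, 74.0 to 99.9%). An intronic CpG of Akt2, a kinase of insulin signalling, at position 27292119 of chromosome 7 was at 40.0% (20 reads) against 100% (30 reads). Methylation was higher at an exonic CpG of Tbc1d1, a regulator of GLUT4 traffic, at position 64317822 of chromosome 5 (39.4% of 99 reads against 2.04% of 49 reads), and at an intronic CpG of the growth factor receptor gene Igf1r at position 67680638 of chromosome 7 (37.7% of 61 reads against 6.06% of 66 reads).

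Calcium handling and excitation had 6 called members of 48, with 4 lower and 2 higher. Lower sites were in the 3' UTR of Adrb1, the main cardiac beta-adrenergic receptor (position 56712714 of chromosome 19, 12.4% against 83.3%, the latter from 12 reads), and in the 5' UTR of Kcnd3, a channel of the transient outward potassium current (position 105359720 of chromosome 3, 41.8% against 96.9%). Lower intronic sites were in the sodium channel subunit gene Scn4b (position 45057344 of chromosome 9, 61.1% against 98.8%) and in Jph2, which anchors the sarcoplasmic reticulum to the plasma membrane (position 163205083 of chromosome 2, 46.9% against 100%). The intronic CpG of Itpr1 at position 108433857 of chromosome 6 stood at 77.6% in mG4H-OFF (49 reads, 63.4 to 88.2%) and at 0% in Con-OFF (29 reads, 0 to 11.9%). An intronic CpG of Cacna1c, the pore of the L-type calcium channel, at position 119177025 of chromosome 6 stood at 96.9% (32 reads) against 50% (26 reads).

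All 4 called members of the 40 hypertrophy and stress genes were lower. They were Ednra in its 5' UTR (position 78450921 of chromosome 8, 9.88% of 81 reads against 100% of 23 reads), the cardiac transcription factor genes Gata6 (position 11049475 of chromosome 18, 24.6% against 90%) and Gata4 (position 63485247 of chromosome 14, 5.56% against 20.4%), and the kinase gene Mapk3 (position 126362308 of chromosome 7, 72.4% against 96.2%). Among the 38 genes of matrix and fibrosis, Smad7, an inhibitor of transforming growth factor beta signalling, had the only called site, at its promoter (position 75500814 of chromosome 18, 40.1% of 157 reads against 97.7% of 86 reads). Synpo2l, which encodes a cytoskeletal protein of the Z-disc, had the only called site among the 34 sarcomere genes (position 20711357 of chromosome 14, 44.1% against 98.9%).

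Histone modifying enzymes had 6 called members of 45, of which 5 had lower sites. Jarid2 had 6 called CpGs within an intron between positions 45023108 and 45023176 of chromosome 13. At 45023176 the level was 34.5% in mG4H-OFF (386 reads, 29.7 to 39.4%) and 100% in Con-OFF (81 reads, 95.5 to 100%), while the 4 sites from 45023108 to 45023130 were lower by smaller amounts, for example 41.4% against 58.0% at 45023108. The acetyltransferase genes Kat2a (position 100602962 of chromosome 11, 16.8% against 92.0%) and Kat2b (position 53874147 of chromosome 17, 67.7% against 95.5%) and the demethylase genes Kdm2b (position 123039177 of chromosome 5, 43.3% against 95.7%) and Kdm6a (position 18029475 of chromosome X, 31.0% against 96.1%) were lower too. Suz12, a core Polycomb subunit, was higher in an intron (position 79888443 of chromosome 11, 51.5% against 1.75%). Among 23 genes of DNA methylation and demethylation, Tet2 was higher in an intron (position 133187542 of chromosome 3, 74.2% of 31 reads against 11.8% of 51 reads) and the methyl-CpG binding factor gene Zbtb38 was lower (position 96601534 of chromosome 9, 33.3% of 24 reads against 100% of 16 reads).

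**Figure D2:**
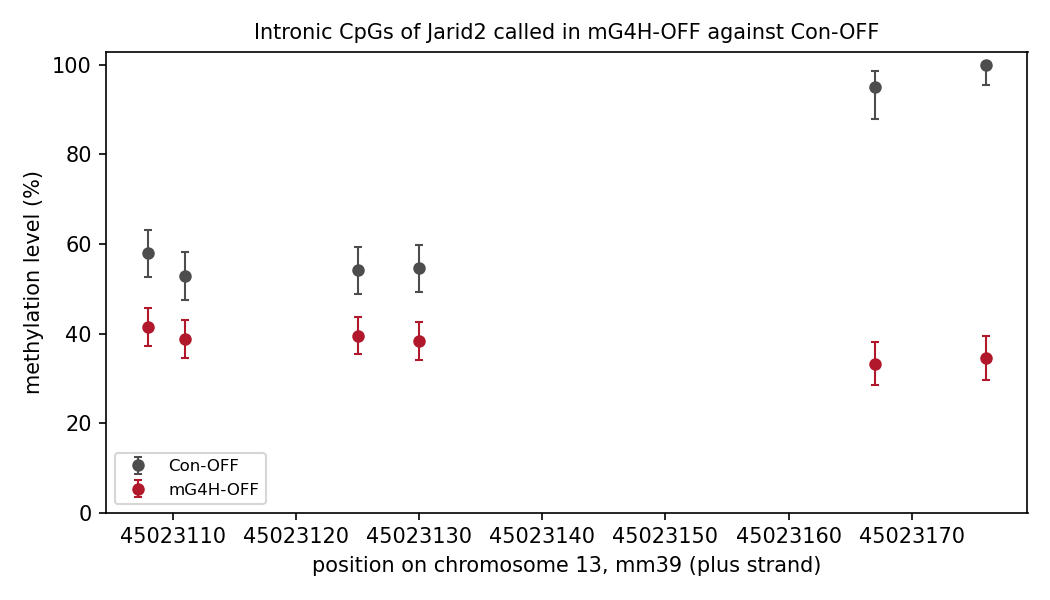
Methylation level (y axis, %) of the 6 called intronic CpGs of Jarid2 by position on chromosome 13 of mm39 (x axis) in the pooled mG4H-OFF and Con-OFF libraries, with exact 95% binomial intervals that cover counting error only. The level in Con-OFF is 52.9 to 58.0% at the 4 sites on the left and 95.1% and 100% at the pair on the right, and mG4H-OFF lies between 33.2% and 41.4% at all 6.

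Fatty acid genes had called sites in introns of the heart fatty acid binding protein gene Fabp3, which was higher (position 130202917 of chromosome 4, 24.2% of 124 reads against 2.70% of 74), and of the nuclear receptor gene Esrrb, which was lower (position 86468862 of chromosome 12, 52.2% of 92 reads against 100% of 67). Pgm3 of the hexosamine pathway was lower at its promoter (position 86453888 of chromosome 9, 41.1% of 129 reads against 68.9% of 106), as was the mitochondrial transhydrogenase gene Nnt in its 5' UTR (position 119545539 of chromosome 13, 40% of 165 reads against 81.9% of 94). The clock-linked repressor gene Nfil3 was higher in an intron (position 53134508 of chromosome 13, 50.4% of 113 reads against 3.51% of 57). Of the imprinted genes, Cdkn1c (position 143014074 of chromosome 7, 21.4% of 28 reads against 100% of 15) and H13 (position 152511153 of chromosome 2, 27.0% of 37 reads against 73.8% of 61) were lower and Mkrn3 (position 62070007 of chromosome 7, 28.2% of 195 reads against 10.7% of 168) was higher. Of the cell type markers, the fibroblast gene Gsn was lower (position 35158312 of chromosome 2, 17.6% of 51 reads against 100% of 11) and the pericyte gene Pdgfrb higher (position 61201366 of chromosome 18, 41.9% of 86 reads against 9.80% of 51). No gene of glucose transport and glycolysis or of pyruvate entry had a called site in this comparison, and none of the markers of cardiomyocytes, endothelium, leukocytes, Schwann cells and neurons, adipocytes and epicardium, or erythroid cells had one. Slc2a4, the gene of GLUT4, and Myh6, the gene of alpha myosin heavy chain, had 2 and 4 sites listed at p under 0.05, each with q = 1 in the authors' deposited table.

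Over all listed sites of a gene list, the median difference of calcium handling and excitation was 11.4 percentage points (125 of 213 sites higher), at percentile 97.6 among 10000 random gene lists matched on their numbers of listed sites. It was not outside their central 95% without chromosomes X and Y, with promoter and 5' UTR sites only, or with called sites only. Among the 71 such medians computed in the 3 comparisons, 5 lay outside the central 95% of random lists and 3.55 would by chance, so this and the like values below describe these libraries and carry no test across animals.

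Genes with several called sites, and the single sites with the widest differences, were mostly outside these lists. Sfi1, a centrosome gene, had 4 promoter CpGs between positions 3143627 and 3143672 of chromosome 11 with median levels of 70.7% in mG4H-OFF and 0% in Con-OFF. Coverage at these 4 was 370 to 408 reads in mG4H-OFF and 17 to 19 in Con-OFF, a ratio far above the usual range. Another CpG of Sfi1 at position 3143429 was lower (66.4% of 937 reads against 95.2% of 147 reads). Itga6, an integrin gene, had 3 lower exonic CpGs between positions 71617323 and 71617338 of chromosome 2 (median difference -51.6 percentage points). Rere, a transcriptional corepressor gene, had 3 lower intronic CpGs between positions 150399929 and 150399961 of chromosome 4 (median difference -67.9 percentage points, with 10 reads at each site in Con-OFF). Nrp1, which encodes a co-receptor of vascular growth factors, had 3 lower sites, of which the CpG island site at position 129083812 of chromosome 8 stood at 38.7% against 94.9%. The widest loss was at the promoter of Naa35 (position 59733090 of chromosome 13, 4.84% of 124 reads against 100% of 12 reads) and the widest gain in an intron of Catspere1 (position 177703818 of chromosome 1, 92.3% of 26 reads against 0% of 10 reads). A CpG in an intron of Vdac3, a channel of the outer mitochondrial membrane, was also among the 5 widest gains (position 23083434 of chromosome 8, 86.5% against 0%).

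The ribosomal RNA genes Rn45s and Rn18s on chromosome 17 held the deepest called sites and went both ways. At position 40156673 the level was 13.8% in mG4H-OFF (7952 reads) and 35.0% in Con-OFF (5385 reads), and at position 40158235 it was 27.7% (6291 reads) and 14.5% (5962 reads). These genes stand in many copies whose reads cannot be assigned to a copy, and without them 986 sites were called, 334 of them higher.

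Called sites merged within 500 bp made 932 regions, of which 94.2% held a single CpG and 14 held at least 3. Coverage at the called sites was higher in mG4H-OFF than in Con-OFF (median ratio 1.40, 1.35 to 1.45), whereas at listed sites that missed the q threshold the median ratio was 0.906. The ratio exceeded 1.52, the 90th percentile of those other sites, at 447 of the 1026 called sites and at 23 of the 42 called sites of list genes. Among these 23 were the sites of Uqcrc2, Idh3a, Mdh2, Prkag2, Ednra, Adrb1, Smad7, Itpr1 and the 2 widest differences in Jarid2. The sites of Akt2, Igf1r, Cacna1c, Scn4b, Suz12, Tet2, Gata4 and Kat2b lay in the usual range, and 569 called sites of all genes remained when only sites in the 10th to 90th percentile were counted.

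The comparison of mG4H-ON with Con-OFF addressed methylation during glucose delivery. These libraries differed in genotype and also in DOX schedule. Methylation differed at 836 CpG sites annotated to 728 genes, lower in mG4H-ON at 495 and higher at 341, which is a share of higher sites of 40.8% (37.4 to 44.2%). Some of the genes named above for mG4H-OFF had the same site called here in the same direction, among them Uqcrc2, Idh3a, Mdh2, Prkag2, Ednra and Jarid2 with lower and Itpr1, Suz12 and Tet2 with higher methylation. The median size of the difference was 45.5 percentage points.

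Called sites were found in 14 of the 24 gene lists, in 33 genes. Oxidative phosphorylation was the only list with a number of called members outside the central 95% of random lists (4 against a mean of 1.25, percentile 97.9), and histone modifying enzymes had 6 against 2.70 (percentile 97.2). About 1 of the lists would lie outside by chance, and the coverage ratios at the sites of Uqcrc2, Idh3a and Mdh2 (2.32, 4.71 and 8.67) were above the usual range. In oxidative phosphorylation and mitochondrial biogenesis 4 of 46 members were called, with Uqcrc2 at 11.4% (44 reads) against 100%, Idh3a at 18.2% (66 reads) against 100%, and Mdh2 at 30.8% (104 reads) against 100%. A CpG in the 3' UTR of Polg, the mitochondrial DNA polymerase, was higher (position 79099182 of chromosome 7, 98.7% of 77 reads against 75.3% of 73 reads). In calcium handling, Adrb1 (5.56% against 83.3%), Kcnd3 (31.3% against 96.9%) and Scn4b (67.9% against 98.8%) were lower and Itpr1 (61.2% against 0%) was higher. Of the hypertrophy and stress genes, Ednra (8.82% against 100%) and Gata6 (28.0% against 90%) were lower, and an intronic CpG of Hdac9, a histone deacetylase of striated muscle, was higher (position 34476314 of chromosome 12, 82.4% of 17 reads against 0% of 11 reads).

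In insulin and growth signalling, the promoter CpG of Prkag2 stood at 10.6% (66 reads) against 94.7%, and a further CpG of Prkag2 at position 25200697 of chromosome 5 was higher (54.2% of 24 reads against 5.13% of 39 reads). Akt2 was lower (33.3% against 100%) and Tbc1d1 higher (41.4% against 2.04%). Of the histone modifying enzymes, the Jarid2 sites at 45023167 (40.7% against 95.1%) and 45023176 (40.9% against 100%), Kat2a (21.3% against 92.0%), Kdm2b (40.0% against 95.7%) and Kdm6a (51.3% against 96.1%) were lower. Suz12 (40.5% against 1.75%) and Hdac9 were higher. Tet2 was higher again (58.1% against 11.8%). Smad7 was lower (43.1% against 97.7%), and an intronic CpG of Col4a2, a collagen of the basement membrane, was higher (position 11418265 of chromosome 8, 63.6% of 22 reads against 0% of 18 reads).

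Other called list members were Fabp3 (38.6% against 2.70%), Nfil3 (40.8% against 3.51%) and Mkrn3 (29.3% against 10.7%), which were higher. The lower ones were Esrrb (65.3% against 100%), Synpo2l (49.2% against 98.9%), Nnt (50.3% against 81.9%), Cdkn1c (22.2% against 100%), Gsn (16.7% against 100%) and the imprinted gene Dlk1 (position 109419893 of chromosome 12, 10.5% of 19 reads against 87.5% of 16). Among endothelial markers, the promoter of the vascular growth factor receptor gene Flt1 was higher (position 147663031 of chromosome 5, 67.3% of 49 reads against 4.76% of 21 reads) and an intronic CpG of the transcription factor gene Sox17 was lower (position 4563972 of chromosome 1, 55.4% against 86.1%, 101 reads each). Over its 52 listed sites the endothelial list had a median difference of -15.4 percentage points, at percentile 2.25 of random lists, and it was not outside their central 95% with promoter and 5' UTR sites only or with called sites only. Slc2a4 had no site listed at p under 0.05, and the 4 listed sites of Myh6 had q of at least 0.893 in the authors' deposited table.

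Outside the lists, the promoter of Septin11, a cytoskeletal GTPase gene, had the widest loss (position 93240965 of chromosome 5, 5% of 40 reads against 100% of 29 reads). The widest gain was in an exon of Ccno, a cyclin gene next to the ciliogenesis regulator gene Mcidas (position 113126325 of chromosome 13, 93.9% of 49 reads against 0% of 10 reads). Lef1, a transcription factor gene of the Wnt pathway, was higher upstream of its start (position 130902915 of chromosome 3, 91.3% against 5.26%), and 2 promoter CpGs of the small GTPase gene Hras were higher (66.0% against 0% at position 140774934 of chromosome 7 and 46.4% against 5.88% at position 140774841).

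The annotation of the called sites resembled that of mG4H-OFF, with 42.5% in CpG islands against 9.56% of the sites that missed the q threshold (Fisher's exact test, adjusted p = 8.99e-133) and 26.4% in promoters against 5.25% (adjusted p = 3.46e-86). The sets were again not matched on depth. Coverage was again higher at called sites. The median ratio of mG4H-ON to Con-OFF was 1.21 (1.17 to 1.25) there and 0.706 at the other listed sites. The ratio was above 1.20, their 90th percentile, at 423 of the 836 called sites and at 23 of the 35 called sites of list genes, and the 406 sites in the 10th to 90th percentile were 222 higher and 184 lower, a share of higher sites of 54.7% (49.7 to 59.6%).

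The overlap of these lists addressed which differences were present during glucose delivery and still present 2 weeks after its end. Of the 1026 sites called in mG4H-OFF and the 836 called in mG4H-ON, 660 were called in both, 433 of them lower and 227 higher in both mG4H libraries, with none in opposite directions. Shared sites included those of Uqcrc2, Idh3a, Mdh2, Prkag2, Ednra, Adrb1, Kcnd3, Itpr1, Smad7, Suz12 and Tet2. Of these, only Suz12 and Tet2 had a coverage ratio of mG4H-OFF to Con-OFF in the usual range. Independent lists of these lengths would share 0.0509 higher and 0.138 lower sites. Simulated libraries with no difference, drawn with the real coverages and compared with a common control, shared 0 sites at the same thresholds over 2410506 simulated sites. Part of the overlap may still come from the common Con-OFF library, which could not be split, and both mG4H libraries differed from it in genotype.

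The mG4H libraries had similar levels at the shared sites. These sites were selected for differing from the same Con-OFF level in both libraries, which favours like levels, so the values here describe them and test nothing. At the sites with higher methylation, the median was 1.72% in Con-OFF, 42.9% in mG4H-ON and 39.0% in mG4H-OFF, and at the sites with lower methylation it was 97.6%, 45.2% and 42.9%. At 252 of the 660 sites the coverage ratios to Con-OFF lay in the usual range in both comparisons, 128 of them higher and 124 lower. The median of mG4H-OFF minus mG4H-ON was -1.25 percentage points, and 85.3% of the sites lay within 10 points of each other. Of the 660 sites, 35 (5.30%) were listed between mG4H-OFF and mG4H-ON at p under 0.05, and none was called. Beyond the shared sites, 980 of the 1026 sites called in mG4H-OFF were listed in mG4H-ON at p under 0.05, and 814 of the 836 called in mG4H-ON were listed in mG4H-OFF.

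**Figure D3:**
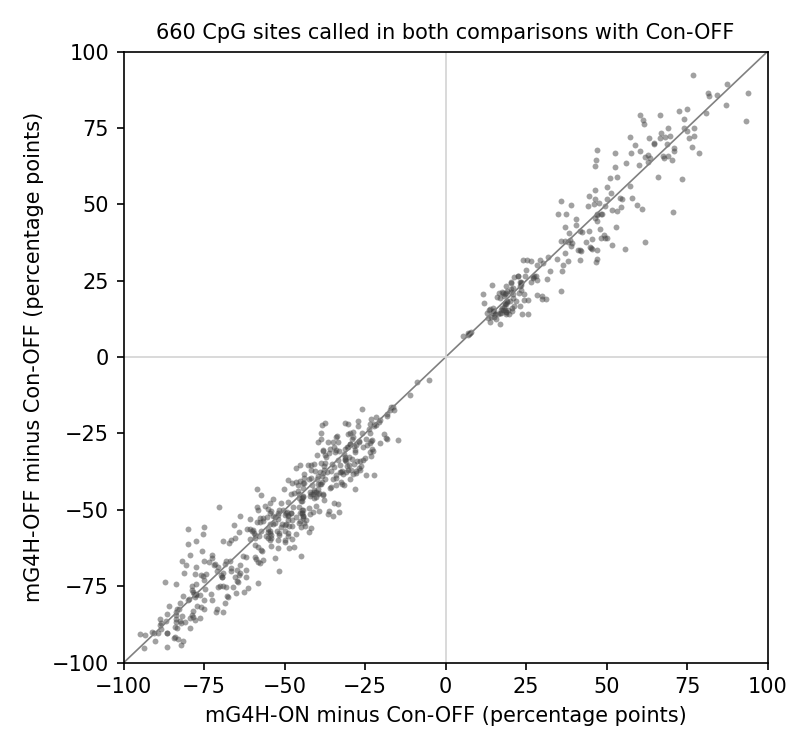
Difference from Con-OFF in mG4H-ON (x axis, percentage points) against the difference in mG4H-OFF (y axis, percentage points) at the 660 CpG sites called in both comparisons, each point being 1 site. All points lie in the quadrants of like sign. In 85.3% of them mG4H-OFF and mG4H-ON were within 10 points of each other, and the median absolute distance was 4.49 points. The selection of sites called against a common Con-OFF level favours such likeness.

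Genes with at least 3 shared sites, apart from the ribosomal RNA genes, included Sfi1, Bmpr2, Flrt2, Nfix and Orai1. In the 5' UTR of Bmpr2, the type II receptor of bone morphogenetic proteins, the CpG at positions 59803704 and 59803705 of chromosome 1 went opposite ways on its strands. The plus strand stood at 84.2% in Con-OFF, 14.9% in mG4H-ON and 9.38% in mG4H-OFF, and the minus strand at 2.17%, 55.6% and 61.1%. In an island of Nfix, a transcription factor gene, positions 85511035 and 85511036 of chromosome 8 showed the same kind of split, with 96.6%, 46.6% and 36.1% on the plus strand and 0.781%, 35.3% and 32.8% on the minus strand. Orai1, a store-operated calcium channel gene, had it at positions 123153361 (97.2%, 50.7% and 39.3%) and 123153362 (2.94%, 26.3% and 25%) of chromosome 5. At each of these CpGs the strands already stood near opposite extremes in Con-OFF. In mG4H-OFF the strands lay close together at Nfix (36.1% and 32.8%) and far apart at Bmpr2 (9.38% and 61.1%).

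Shared genes also had called sites exactly 45 bp apart, on the minus strand and then the plus strand, with the same direction at each. They included the promoter of the adhesion gene Flrt2 (positions 95658851 and 95658896 of chromosome 12), the planar polarity gene Prickle1 (93417267 and 93417312 of chromosome 15), Ccno and Mcidas (113126280 and 113126325 of chromosome 13), and Tgfbrap1, which encodes a protein associated with the transforming growth factor beta receptor (43132035 and 43132080 of chromosome 1), and the minus strand site of Nfix was followed in the same way by a plus strand site at 85511081. In Prickle1 the levels in Con-OFF, mG4H-ON and mG4H-OFF were 1.05%, 17.9% and 20.4% at the minus strand site and 0%, 87.5% and 89.5% at the plus strand site, where Con-OFF had 11 reads.

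The comparison of mG4H-OFF with mG4H-ON addressed how methylation after the end of glucose delivery differed from that during it. These libraries also differed in the presence of DOX itself and in the time since DOX was started. A difference between them therefore cannot be assigned to the end of glucose delivery. Among the listed sites, 12 were called, 7 lower and 5 higher in mG4H-OFF. The implied ranks put 42 sites at q under 0.1 in this comparison, and 23 of these were not listed, so further called sites may be missing here. Lower methylation was found at 3 neighbouring CpGs in the promoter island shared by Tmem267, a transmembrane protein gene, and 3110070M22Rik, and at an intronic CpG of Ddah1, which encodes an enzyme that degrades an inhibitor of nitric oxide synthesis. Higher methylation was found at an intronic CpG of Lrrc4c, a synaptic adhesion gene. No gene of the 24 lists had a called site among the sites listed in this comparison.

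At Tmem267, positions 119624954, 119624969 and 119624976 of chromosome 13 stood at 42.0%, 46.4% and 44.5% in mG4H-OFF and at 61.5%, 64.9% and 63.7% in mG4H-ON, with 339 to 379 reads at each. At Ddah1, position 145571470 of chromosome 3 stood at 73.9% in mG4H-OFF (222 reads) and 89.4% in mG4H-ON (511 reads). At Lrrc4c, position 97076698 of chromosome 2 stood at 64.5% (726 reads) and 43.9% (173 reads). Intergenic called sites were position 128625160 of chromosome 8 (88.1% against 50.6%) and positions 109460808 (23.4% against 44.4%) and 163352100 (29.3% against 67.0%) of chromosome X. The remaining 4 called sites were in the ribosomal RNA genes Rn45s and Rn18s, and without them 8 sites were called, 2 of them higher.

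Among listed sites that were not called, those of glucose transport and glycolysis had a median of 19.04 percentage points between mG4H-OFF and mG4H-ON (24 of 38 sites higher, percentile 99.5 of random lists). Both listed sites of Slc2a4 had higher values in mG4H-OFF, 82.6% of 23 reads against 38.5% of 13 reads in its 3' UTR (position 69833650 of chromosome 11) and 39.1% of 23 reads against 9.52% of 21 reads in an intron (position 69838447). So had 5 of the 7 listed sites of Hk1 and 3 of the 4 of Hk2, the hexokinase genes, and both of Pfkm, the muscle phosphofructokinase. Of the 19 members with a listed site, 8 had a negative median, among them Mlxipl (-37.5 points), Slc2a12 (-20 points), Pfkp (-14.6 points) and Gapdh (-8.58 points). The list of pyruvate dehydrogenase and mitochondrial pyruvate entry had 8 of 9 listed sites higher, 5 of them in Pcx, the pyruvate carboxylase gene (median 26.3 points, percentile 97.7). The histone modifying enzymes had 60 of 98 listed sites lower (median -12.5 points, percentile 1.54), including all 6 of Hdac7 and all 4 of Hdac5, while their relatives among the class IIa histone deacetylases went both ways (3 of 5 higher in Hdac9, 2 of 4 in Hdac4). None of these sites passed the q threshold. Slc2a4 and Myh6 were listed beforehand as loci homologous to the transgene, and whether reads of the transgene entered at their sites was not examined. The 3 listed sites of Myh6 had q = 1 in the authors' deposited table. Without chromosomes X and Y only the glucose transport list stayed outside the central 95%, at percentile 99.5, and with promoter and 5' UTR sites only none of these 3 lists did.

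The share of higher sites among the 12 called was 41.7% (15.2 to 72.3%). CpG islands held 6 of the 12, which came from 2 loci, the Tmem267 promoter and the ribosomal RNA genes. In simulated libraries with this pair's coverages, planted differences of 10, 25 and 50 percentage points were recovered at 4%, 32% and 66% of sites. That simulation adjusted over 20000 sites and not over 2391223, so its threshold was laxer and these shares are too high for the deposited calls. Most differences of 25 points or less would thus go uncalled at this depth.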

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

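The test in this part is the authors' test between mG4H-OFF and mG4H-ON, which was not chosen after the result was seen. Each site below was called in 1 mG4H library against Con-OFF, and the difference between the mG4H libraries was itself called, which is why it is given here as a difference between groups. The test is on reads of 1 library per group and covers counting error only, so it does not show a difference between the ON and OFF stages.

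Higher methylation called against Con-OFF only in mG4H-ON stood at Ddah1 (position 145571470 of chromosome 3), with 69.0% in Con-OFF, 89.4% in mG4H-ON and 73.9% in mG4H-OFF, a difference of -15.6 percentage points between mG4H-OFF and mG4H-ON. Lower methylation called only in mG4H-ON stood at Lrrc4c (position 97076698 of chromosome 2), with 65.9%, 43.9% and 64.5% in that order, a difference of 20.5 points, and at the intergenic position 128625160 of chromosome 8, with 94.9%, 50.6% and 88.1%, a difference of 37.4 points. Lower methylation called only in mG4H-OFF stood at the intergenic position 109460808 of chromosome X, with 41.4%, 44.4% and 23.4%, a difference of -21.0 points. Among the ribosomal RNA genes, Rn45s and Rn18s differed by 11.1 points at position 40154258 of chromosome 17 (44.3%, 43.1% and 54.2%), by 5.98 points at 40154618 (30.0%, 32.1% and 38.0%) and by -5.73 points at 40155913 (14.0%, 19.9% and 14.2%). No explanation of these differences was tested, and each rests on 1 pooled library per group.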

How the results depend on the processing

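The settings on Rn45s, on control levels and on the coverage ratio were chosen after the results were seen, and the others before the data were examined. No paired analysis was possible because each group had 1 pooled library. In the usual coverage ratio the excess of lower sites was gone for mG4H-ON against Con-OFF (222 higher, 184 lower, a share of 49.7 to 59.6% higher). It was also gone for shared sites (128 higher, 124 lower). At p under 0.05 the split was near even in every comparison (24330 higher and 24282 lower, 22766 and 22718, 19577 and 19108). The same held for shared sites (4597 and 4561), and the cause was not tested. The counts of called sites in mG4H-OFF and mG4H-ON against Con-OFF and of shared sites stayed within 1.5 times of 1026, 836 and 660 at q under 0.05 (866, 750 and 593), at 20 reads (867, 694 and 562), without X and Y (1006, 816 and 644), without Rn45s and Rn18s (986, 820 and 646) and as regions (932, 778 and 615). Depth limited the named sites, of which 97 of 126, 59 of 89 and 12 of 12 were still called at 20 reads in the 3 comparisons. In the usual coverage ratio 61 of 126, 30 of 89 and 8 of 12 remained, and without extreme levels in Con-OFF 59 of 126 and 25 of 89.

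At p under 0.05 without correction the counts were 48612, 45484 and 38685 (mG4H-OFF against mG4H-ON) with 9158 shared, and the shares of higher sites 50.05% in both, and the cause of the latter was not tested. Fisher's exact test adjusted over the listed sites gave 48627, 45514, 38705 and 9161 shared, because it adjusts over far fewer sites. Counting every annotation line gave 4147, 3420, 46 and 2820 shared, because a site has a line for each annotation. At q under 0.01 the counts were 680 (mG4H-OFF against Con-OFF) and 5 (mG4H-OFF against mG4H-ON), and for the latter 19 with no minimum difference and 2 at 25 points. These follow from the thresholds. Without sites at 10% or less or 90% or more in Con-OFF there were 271, 136 and 90 shared, because fewer sites remained. In the usual coverage ratio there were 569, 406 and 252 shared, with 40.4% and 54.7% higher, and the cause was not tested. The number of gene lists outside the central 95% was 0 for mG4H-OFF against Con-OFF both in promoters and 5' UTRs and without X and Y, in place of 1 (calcium handling). For mG4H-OFF against mG4H-ON it was 1 (sarcomere) in promoters and 5' UTRs and 1 (glucose transport) without X and Y, in place of 3. For mG4H-ON it stayed at 1 in promoters and 5' UTRs, but with imprinted genes in place of endothelium. With called sites only it stayed at 1 in both comparisons with Con-OFF, but with oxidative phosphorylation (percentiles 0.56 and 0.88) in place of calcium handling and endothelium. The cause was not tested. Called sites only gave no list value for mG4H-OFF against mG4H-ON, as no member was called.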

Other observations

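The sites in this part were chosen after the results were seen, as were the tests of read numbers and strands, while the tests of neighbours, of spread and of the overlap at p under 0.05 were planned before their values were seen. Of the 1026 sites called in mG4H-OFF, 46 were not listed in mG4H-ON at p under 0.05, and 40 of these were listed between mG4H-OFF and mG4H-ON with the matching direction. Among them, methylation was lower in mG4H-OFF at Wnt11, a signalling ligand of heart development (position 98484655 of chromosome 7, 31.0% in Con-OFF, 20.2% in mG4H-ON and 4.26% in mG4H-OFF), at the procollagen peptidase gene Adamts2 (position 50493910 of chromosome 11, 28.6%, 20.3% and 5.95%), at the RNA helicase gene Mov10 (position 104713046 of chromosome 3, 28.9%, 24.2% and 0%), at the Itga6 CpG at position 71617338 of chromosome 2 (68.3%, 52.8% and 16.7%) and at the glutathione transferase gene Gstt2 (position 75669115 of chromosome 10, 55.3%, 30.0% and 0%). It was higher at Ace, the angiotensin converting enzyme gene (position 105858389 of chromosome 11, 61.7%, 65.8% and 87.7%), at the proteoglycan gene Acan (position 78751668 of chromosome 7, 64.8%, 73.8% and 86.0%), at the skeletal myosin gene Myh2 (position 67081258 of chromosome 11, 70.2%, 82.1% and 100%) and at the hydrolase gene Abhd2 (position 78923210 of chromosome 7, 58.2%, 58.4% and 84.4%). Coverage in mG4H-OFF at these sites was 19 to 143 reads.

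Of the 836 sites called in mG4H-ON, 22 were not listed in mG4H-OFF, and 21 of these were listed between mG4H-OFF and mG4H-ON in the direction of a return toward Con-OFF. The choice of these sites largely fixes that direction, as it does for the 40 of 46. Next to the Ddah1 site named above, position 145571262 stood at 74.8% in Con-OFF, 90.1% in mG4H-ON and 79.4% in mG4H-OFF. Polg (75.3%, 98.7% and 88.5%), the folate transporter gene Slc46a1 (position 78358552 of chromosome 11, 9.21%, 42.0% and 16.9%) and the volume-regulated channel gene Lrrc8d (position 105849358 of chromosome 5, 0%, 30.3% and 3.23%) were called as higher in mG4H-ON and not listed in mG4H-OFF. The homeobox gene Dlx2 (position 71375678 of chromosome 2, 98.9%, 76.9% and 93.7%), the neuropeptide receptor gene Vipr1 (position 121479392 of chromosome 9, 75%, 7.14% and 50%) and the cannabinoid receptor gene Cnr2 (position 135626035 of chromosome 4, 73.9%, 16.1% and 45.9%) were called as lower in mG4H-ON and not listed in mG4H-OFF, although the levels in mG4H-OFF were also below Con-OFF.

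The shared sites were weighed against chance, base differences and added reads, and simulated libraries with no difference shared 0 sites where 660 were observed, but the simulation holds counting error only, so a chance deviation of the single Con-OFF library stays open. Reads in the Con-OFF state were counted at 568 shared sites near 0 or 100% in Con-OFF. In mG4H-OFF they numbered 0.824 times those of Con-OFF (0.802 to 0.844), where the same levels planted on other sites gave 0.328. Only the 13041 of 20000 planted sites that passed the p cutoff entered the planted value, which favours larger drops. The gap in these reads therefore does not decide on a change of methylation. The median coverage ratio itself was 1.62 at the shared sites and 0.931 at the planted ones. The planted sites were not matched on annotation class, so an allele in place of that of Con-OFF, or a change of methylation, together with unequal coverage stays open. Of the neighbours within 50 bp listed in any comparison, 53.0% (43.5 to 62.3%) were listed in mG4H-OFF against Con-OFF with the same direction. At other listed sites it was 57.6%. The remainder includes neighbours not listed in this comparison, and neighbours listed in no comparison could not enter. The share therefore does not decide on a base difference at 1 cytosine. Alleles segregating among the pooled animals stay open, since the spread of mG4H-OFF minus mG4H-ON (excess SD over the binomial expectation -2.72 points, -3.61 to -0.813) was taken at sites selected for being alike in both libraries and decides nothing. At 252 shared sites coverage ratios were usual. At the 214 of them near 0 or 100% in Con-OFF, reads in the Con-OFF state were again above the planted value (0.743 against 0.503 in mG4H-OFF, 0.618 against 0.373 in mG4H-ON). Their median coverage ratios were still above the planted ones (1.13 against 0.95 in mG4H-OFF, 0.943 against 0.723 in mG4H-ON). Only the planted sites that passed the p cutoff entered (9433 and 8973 of 20000), so this gap decides nothing either. Whether glucose delivery left a lasting change there or the genotype made the difference stays open, since both mG4H pools differed from Con-OFF in genotype too.

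The strands were weighed for the called sites. Of 9 CpGs called on both strands in mG4H-OFF, 7 went in opposite directions, as in Bmpr2, Nfix and Orai1. The strands of these 7 already stood at opposite extremes in Con-OFF (84.2 to 98.4% and 0 to 10%). The share of opposite directions was 77.8% (40.0 to 97.2%). From such levels the high strand could hardly be called except as lower, and the low strand except as higher. The share therefore does not decide on a base difference that removes these CpGs. Over the 40 called CpGs with both strands listed at p under 0.05 the share was 47.5% (31.5 to 63.9%), and at listed CpGs that missed the q threshold it was 36.4% (32.5 to 40.4%), so opposite strands were common at listed sites in general. Called sites exactly 45 bp apart, minus strand before plus strand, made 18 pairs in mG4H-OFF, all of the same direction, where no other spacing from 20 to 100 bp had more than 2, and 17 pairs in mG4H-ON. The 18 pairs, in Flrt2, Prickle1, Ccno, Tgfbrap1 and others, may come from reads of further fragment ends that join at the same cytosine in some libraries, but fragment ends, and base differences that create them, were not examined because no genome sequence was used.

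The lists at p under 0.05 with more than 5 points shared 4597 higher and 4561 lower sites, with 232 and 231 given by the product of the list lengths over the sites tested, and 28 in opposite directions. Simulated libraries with no difference and a common control shared 14.4% of the mG4H-OFF list (10.9 to 17.0% over sets), where 18.8% was observed. The simulated sites were those listed in more than 1 comparison and not all sites tested, so the 14.4% may not hold for the latter. Most of the observed overlap may come from the common Con-OFF library, and the excess over 14.4% stays open, since 1 library could not be split.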
